A study of Mus musculus with 2 samples.

How the data were processed

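Poly(A)-selected RNA from white adipose tissue was sequenced in 2 libraries, 1 from vehicle-treated and 1 from entacapone-treated C57BL/6 male mice, 23 weeks old, with obesity from a high-fat diet. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was purified with oligo(dT) beads, and libraries were made with the TruSeq RNA v2 kit and sequenced on an Illumina HiSeq instrument. That kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Dose, length of treatment and the number of mice behind each library are not given in the sources used here.

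The authors deposited raw read counts per Ensembl gene for each library, without a header line. TopHat2 2.1.1, HTSeq 0.6.0 and the mouse build mm10 are named in the submitters' processing notes. The annotation release, the counting mode and the treatment of reads that map to several places are not given in the sources used here. Counts of gene families with near-identical members, such as the Mup, Serpina1, globin and metallothionein genes, are therefore uncertain for each single member. Both libraries listed the same 37315 genes, of which 35449 were matched by Ensembl identifier to symbols and GRCm38 positions in GENCODE M21. The 1866 unmatched genes held 0.181% of the vehicle counts and 0.188% of the entacapone counts, and stayed in the library sizes. GRCm38 is the same assembly as mm10.

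The libraries held 13620056 (vehicle) and 12979673 (entacapone) counted reads. CPM values (counts scaled to library size) were computed from the deposited counts with effective library sizes from edgeR 4.0.16 (TMM normalization, factors 1.01 and 0.986). With 1 library per group there is no replicate check and no significance test. No p-value is given, and every difference is one between these 2 libraries, not between the treatments. Each ratio (entacapone over vehicle) carries an exact 95% interval, obtained from the Clopper-Pearson interval of the entacapone share of a gene's reads. These intervals cover counting error only, not variation between mice, dissections or library preparations, and the reads carry no molecular identifiers. At 100 reads per library the interval spans a factor of 1.33 to either side, and at 1000 reads a factor of 1.09. A gene with no read in a library was given a floor of 3 counts there (0.217 CPM in the vehicle and 0.234 CPM in the entacapone library).

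Genes with a mean of at least 1 CPM over both libraries were compared (13361 genes). A gene was counted as different where its ratio reached 2-fold in either direction and its interval excluded 1. For gene lists, the median log2 ratio of the measured members was computed with a pseudocount of 0.5 CPM. Its percentile was taken among 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured members was said to stand apart where that percentile was under 2.5 or over 97.5. In all, 23 pathway lists and 14 cell type marker lists were fixed, and 35 of these 37 had enough measured members. About 1.75 of the 35 would stand apart by chance if list members varied independently. That number does not hold for lists whose members vary together between mice or dissections. Listed symbols that matched no gene (Ighd, Hbb-b1, Hbb-b2 and Muc16) were left out, and Ctgf was matched to Ccn2.

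The gene lists, the limits and the rule for the genes named were fixed before the data were examined. The rule took preset genes, among them Fto, Foxo1, G6pc and Ucp1. It further took, among genes with a mean of at least 5 CPM, the 12 highest and 12 lowest by the interval bound nearest to a ratio of 1, without predicted genes, pseudogenes and antigen receptor segments (2 were passed over among the highest and 1 among the lowest). For each list described it took the 2 highest and 2 lowest measured members. After the values were seen, hepatocyte and keratinocyte and sebaceous gland lists were added. The ranking was also repeated without the genes of these, the skeletal muscle and the epithelium lists. Any other gene named was chosen after its values were seen, and some genes that the rule took are not reported here.

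The ratio intervals and list percentiles were tested on simulated data: counts for 13402 tested genes were drawn from the real means and library sizes, with 200 genes changed 3-fold. In this simulation, 99.0% of the raised and 98.0% of the lowered genes were recovered, and 39 unchanged genes were counted as different. The intervals held the true ratio for 95.5% of genes. Of 100 random lists of 18 genes, 5 stood apart, and all 100 did after a shift of 0.5 on the log2 scale. The simulated counts held counting error only, without variation between mice and with each gene drawn independently. These shares therefore do not carry over to lists whose members vary together. Alternatives were DESeq2 1.42.0 size factors, total counts and upper-quartile scaling; other limits on expression and size; no interval criterion; thinning of the deeper library; other pseudocounts; the mean of members; and leaving out members shared between lists. Removal of the trend with transcript length and GC content, and leaving out the genes of liver, muscle and epithelium, were added after the data were seen. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.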

Results

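Gene expression was compared between subcutaneous (inguinal) white fat of diet-induced obese mice given vehicle and of mice given entacapone. Entacapone is a drug used in Parkinson disease and is also known as an inhibitor of the RNA demethylase FTO. The series addresses which transcripts differ in this fat depot under the drug. Each group held 1 library, so the values below describe 2 libraries and have no replicate error; intervals are exact 95% counting intervals. The vehicle library held 13620056 counted reads over 19166 genes and the entacapone library 12979673 reads over 18932 genes. Mitochondrially encoded transcripts took 4.21% of the vehicle reads and 4.91% of the entacapone reads.

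Most genes were expressed at similar levels. Of 13361 genes with a mean of at least 1 CPM, 85.2% lay within 1.5-fold, and log2 expression correlated across genes with a Pearson r of 0.977 (genes are not independent replicates). At least 2-fold differences beyond counting error were found for 222 genes higher and 468 genes lower in the entacapone library. Differences of any size beyond counting error were common, with 2704 of the 13361 genes higher and 2818 lower. Counts of list members beyond counting error, given below, are to be read against these shares. Cfd, which encodes the secreted protease adipsin, was 3.05-fold higher, and the macrophage marker Adgre1 was lower with a log2 ratio of -1.58 (-1.78 to -1.39). The 12 lowest genes by the fixed ranking included 11 from a list of hepatocyte genes that was added after the values were seen. Without the genes of the liver, muscle and epithelium lists, 200 genes were higher and 429 lower. Of the 35 fixed gene lists with a percentile, 8 stood apart as higher and 12 as lower.

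**Figure D1:**
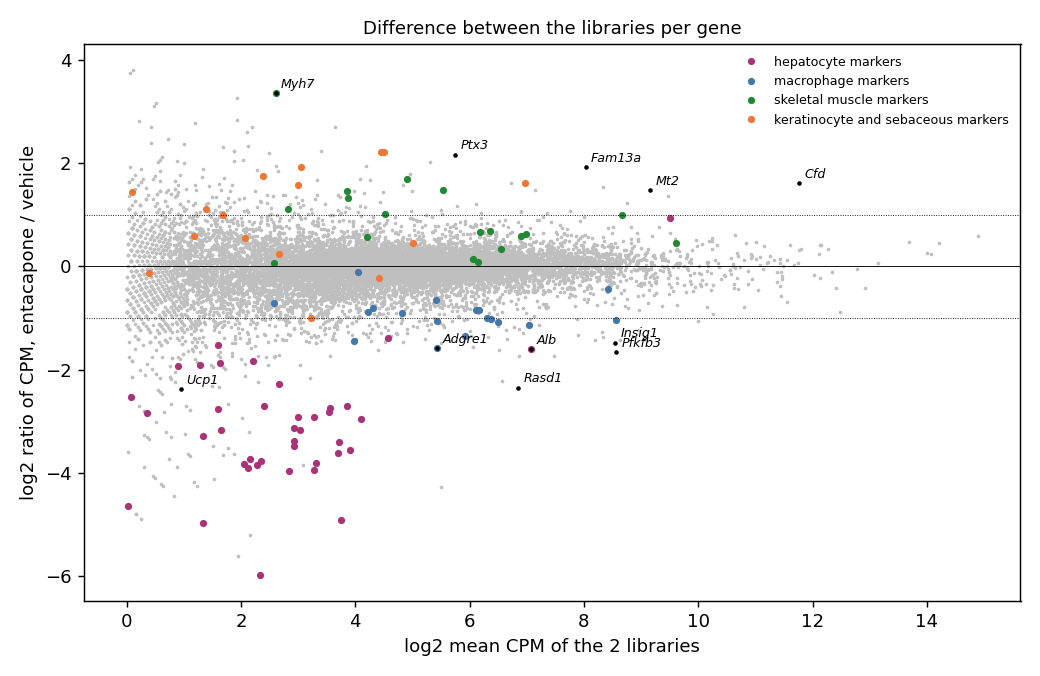
Log2 ratio of CPM (entacapone over vehicle, vertical axis) against log2 mean CPM (horizontal axis) for genes with a mean of at least 1 CPM and reads in both libraries; dotted lines mark 2-fold, and colours mark marker genes of 4 cell types. Macrophage markers lie below 0, with Adgre1 at -1.58, and hepatocyte markers reach -5.99, while Cfd lies at 1.61 among the most abundant genes.

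Fto (chromosome 8, 91313525 to 91668439, GRCm38) stood at 87.5 against 84.6 CPM, and its interval held no difference (log2 0.05, -0.07 to 0.17). Foxo1, the insulin-regulated transcription factor (chromosome 3, 52268336 to 52353221), was also within counting error at 103 against 97.9 CPM (log2 0.08, -0.04 to 0.19). Ucp1, the uncoupling protein of thermogenic fat (chromosome 8, 83290352 to 83298452), was 5.21-fold lower, but on only 8 entacapone and 45 vehicle reads (log2 -2.38, -3.68 to -1.28). G6pc, the catalytic subunit of glucose-6-phosphatase (chromosome 11, 101367561 to 101377903), had 12 vehicle reads and 0 entacapone reads, which is at least 3.71-fold lower against a floor of 3 entacapone counts, while its exact 95% interval reaches down to 2.57-fold. G6pc is a liver enzyme, and liver transcripts were more abundant in the vehicle library.

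The m6A methylation machinery did not stand apart (17 measured genes, median log2 ratio 0.05, percentile 68.9). The reader genes Igf2bp2 (0.79, 0.38 to 1.21) and Ythdf1 (-0.18, -0.34 to -0.03) were beyond counting error. Rbm15 and Ythdc2 were not, with log2 ratios of 0.28 (-0.10 to 0.65) and -0.44 (-0.88 to 0.00). Alkbh5, the other known m6A demethylase, stood at 84.6 against 70.2 CPM. Catecholamine genes stood apart as lower (11 measured, median -0.25, percentile 1.41), with 4 lower and 3 higher beyond counting error. The extraneuronal transporter Slc22a3 was at -0.53 (-0.67 to -0.40), Maoa, a monoamine-degrading enzyme, at -0.43 (-0.59 to -0.26), and Adra2a, an inhibitory adrenergic receptor, at -0.54 (-1.62 to 0.49). Adrb3, the main stimulatory receptor of mouse adipocytes, went the other way at 0.96 (0.86 to 1.05). This call was lost with the mean of the members (-0.015) and with a minimum of 5 CPM (-0.14).

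Thermogenic and brown-fat-like genes were split. Of 18 measured, 8 were lower and 5 higher beyond counting error, with a median of -0.25 (percentile 2.27). Besides Ucp1, the fatty acid transporter Slc27a2 (-5.60, -8.67 to -3.72) and Elovl3, a fatty acid elongase of thermogenic fat (-1.76, -3.36 to -0.42), were lower. Prdm16, a transcription factor of brown fat identity, was at 14.8 against 19.8 CPM. The lipid droplet protein gene Cidea was higher at 43.6 against 23.3 CPM (0.90, 0.70 to 1.11), as were Cox8b (0.84, 0.60 to 1.08), Fabp3 (1.08, 0.34 to 1.85) and the coactivator Ppargc1a (0.84, 0.14 to 1.55). Slc27a2 is also abundant in liver, and Cox8b and Fabp3 in muscle, whose markers differed between the libraries. The list's call was lost with the vehicle library thinned, with a minimum of 5 CPM and with a pseudocount of 0.1. Creatine and calcium cycling did not stand apart (median -0.07, percentile 23.7; the mean was 0.22). Its highest members, Ckmt1 (1.43) and Ckmt2 (1.31), are creatine kinases, and its lowest were Ryr2 (-0.69) and Gatm (-0.51). Muscle and epithelium markers were higher in the same library, and their share in the creatine kinase values was not tested.

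Respiratory chain transcripts were higher together by a small amount. Of 42 nuclear oxidative phosphorylation genes, 38 were higher and 0 lower beyond counting error, with a median of 1.18-fold (log2 0.23, percentile 100.0). With the trend in transcript length and GC content removed, this median was 0.14 (percentile 99.9). Complex I subunits Ndufa5 (0.50, 0.33 to 0.67) and Ndufb10 (0.39, 0.28 to 0.51) were highest, and Cycs (-0.03) and Sdhc (0.04) lowest. Of 13 mitochondrially encoded genes, 11 were higher beyond counting error (median 1.24-fold, log2 0.31, percentile 99.9). Among these, mt-Nd4 was at 0.42 (0.40 to 0.44) and mt-Cytb at 0.40 (0.39 to 0.42), while mt-Nd4l and mt-Nd2 both lay at -0.03. The tricarboxylic acid cycle (median 0.11, percentile 85.7) and fatty acid oxidation (0.11, percentile 84.8) did not stand apart. In the cycle, Ogdh (0.46) and Dlst (0.38), subunits of 1 complex, were highest, and Dlat (-0.22) and Pcx (-0.17) lowest. In oxidation, Echs1 (0.29) and Eci2 (0.27) were highest, and Cpt1a, which controls fatty acid entry into mitochondria, was lowest at -0.72 (-0.83 to -0.61). Skeletal muscle markers, described further on, were higher in the same library.

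Lipid metabolism transcripts diverged. De novo lipogenesis did not stand apart (19 genes, median -0.05, percentile 9.64, mean 0.04). Scd1, a fatty acid desaturase, was at 36573 CPM in the entacapone and 24225 CPM in the vehicle library (0.59, 0.59 to 0.60), and Fads1 was also higher (0.76). Srebf1, the lipogenic transcription factor, was lower (-0.72, -0.78 to -0.66), as was Scd2 (-0.61). Triglyceride synthesis and droplet coat genes were lower beyond counting error in 10 and higher in 7 of 19 (median -0.12, percentile 1.99). The acyltransferases Agpat2 (-1.37, -1.44 to -1.31) and Dgat2 (-0.78, -0.81 to -0.75) were lowest, and Gpat4 (0.62) and Mogat1 (0.44) highest. That call was lost with the mean of the members and with a minimum of 5 CPM. Lipolysis did not stand apart (11 genes, median 0.03, percentile 43.1, mean -0.13). G0s2, an inhibitor of adipose triglyceride lipase, was 2.68-fold lower (-1.42, -1.49 to -1.36) and Abhd15 was at -0.54, whereas the lipase gene Pnpla2 was at 0.41 (0.40 to 0.43) and its coactivator Abhd5 at 0.28.

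Cholesterol synthesis and uptake genes were lower (23 measured, 11 lower and 3 higher beyond counting error, median -0.18, percentile 0.27, mean -0.32). Insig1, the sterol-regulated anchor of this pathway, was 2.79-fold lower at 197 against 550 CPM, and Hmgcs1 was 2.52-fold lower (-1.33, -1.41 to -1.25). Idi1 was higher (0.78, 0.64 to 0.93). Glycolysis and glucose uptake did not stand apart (median 0.01, percentile 31.5). There the transporter Slc2a1 (0.68) and Pfkm (0.62) were highest, and Hk2 (-0.47) and Pfkl (-0.23) lowest. The list of insulin signalling genes and FOXO1 targets was higher (18 measured, 10 higher and 2 lower beyond counting error, median 0.31, percentile 100.0). Skeletal muscle markers were higher in the same library (median log2 ratio 0.67), and their share in this shift was not tested. Cited2 was 3.05-fold higher at 159 against 52.3 CPM, and Klf15, a regulator of amino acid and glucose metabolism, was at 0.93 (0.80 to 1.07). Sesn3 (-0.58) and Irs2 (-0.32), which FOXO1 also activates, were lower, and Pck1 was within counting error.

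Adipokine and adipocyte identity genes went both ways. Of 17 measured, 10 were lower and 6 higher beyond counting error, with a median of -0.17 (percentile 0.60) and a mean of 0.03, which is not below 0. Cfd, which encodes adipsin (chromosome 10, 79890853 to 79892655), was 3.05-fold higher at 5250 against 1722 CPM, and Adrb3 was next at 0.96. Mest, a marker of fat expansion, was lowest at 298 against 697 CPM (-1.23, -1.28 to -1.17), and leptin (Lep) was 4639 against 6209 CPM (-0.42, -0.44 to -0.41). Adipoq, the adiponectin gene, stood at 3118 against 2867 CPM.

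**Figure D2:**
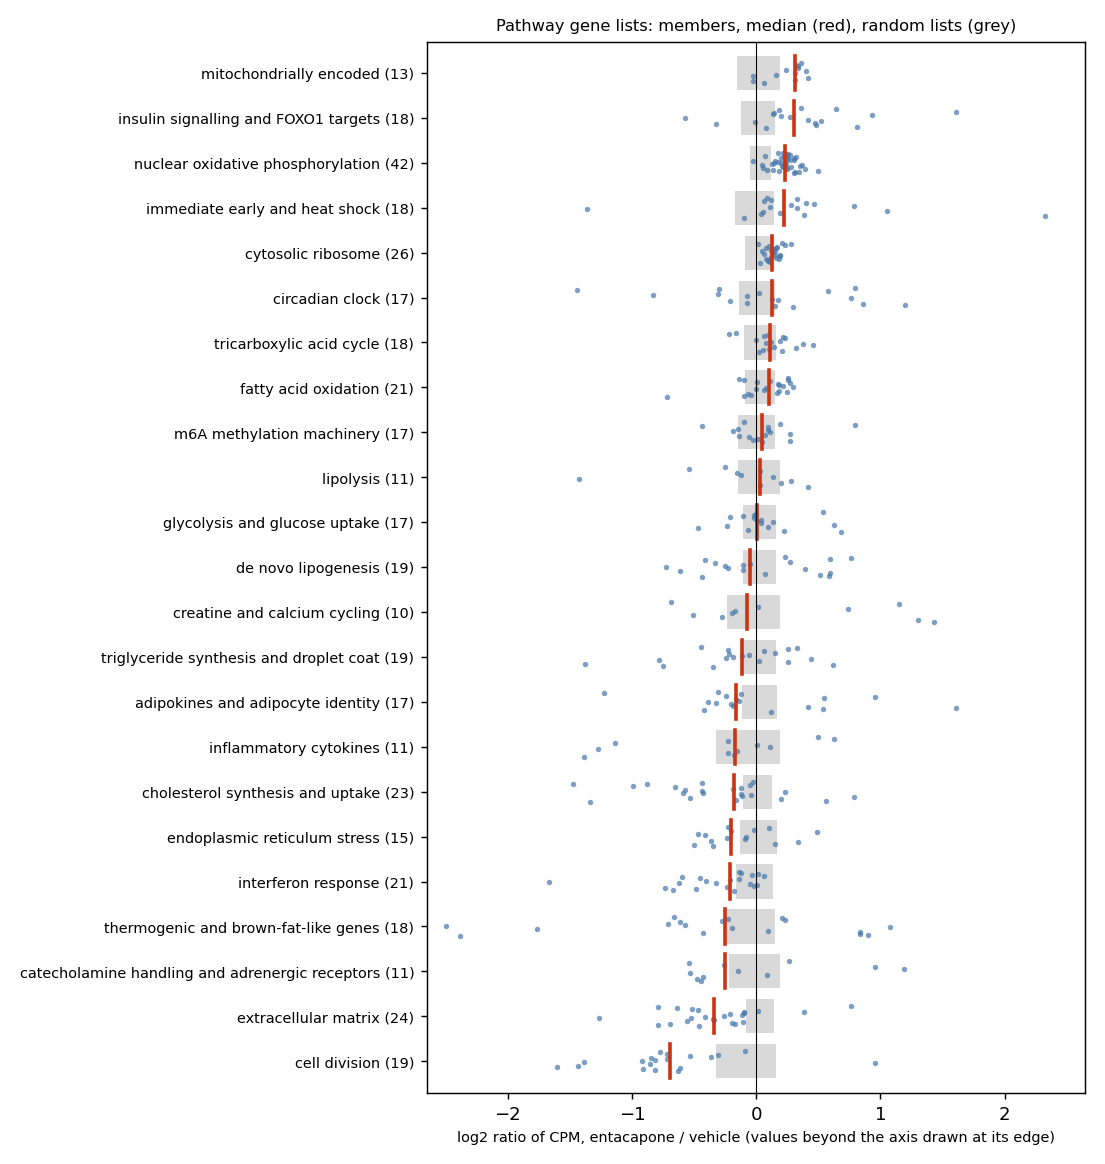
Log2 ratio of CPM (entacapone over vehicle, horizontal axis) for the members of each pathway list (points, without pseudocount; number measured in parentheses), the list median with a pseudocount of 0.5 CPM (red line) and the central 95% of 10000 random lists (grey). The mitochondrially encoded list has the highest median (0.31) and the cell division list the lowest (-0.69).

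Macrophage markers were lower as a group. Of 18 measured, 17 were lower beyond counting error and 8 at least 2-fold, with a median of 1.92-fold (log2 -0.94, percentile 0.0). Adgre1, which encodes a macrophage surface receptor, was at 21.6 against 64.9 CPM, and Trem2, a marker of lipid-associated macrophages, was at 8.52 against 23.1 CPM (-1.44, -1.77 to -1.12). Lyz2, the most abundant marker, stood at 247 against 508 CPM. Cd14 was within counting error, and Lgals3 was at -0.43 (-0.49 to -0.37). Mast cell markers were also lower (6 measured, 4 lower beyond counting error, median -1.12, percentile 0.01), led by the proteases Cma1 (-1.75, -2.33 to -1.20) and Tpsb2 (-1.35, -1.72 to -0.99), with Hdc (0.24) and Kit (0.14) within counting error. Without the expression filter the mast cell median was -0.64. Of 4 measured neutrophil markers, too few for a percentile, Csf3r (-1.09), S100a8 (-1.08) and Mmp9 (-0.86) were lower. Ltf was higher at 17.3 against 3.69 CPM (2.23, 1.79 to 2.70); it is also made by glandular epithelium, whose markers were higher in the same library.

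Fibroblast and matrix transcripts were lower too. Of 14 measured markers of fibroblasts and adipocyte progenitors, 13 were lower beyond counting error (median -0.55, percentile 0.0). The progenitor markers Dpp4 (-1.40, -1.72 to -1.09) and Pi16 (-1.30, -1.41 to -1.19) were lowest, while Pdgfra (-0.01) was within counting error and Ly6a was at -0.20. Of 24 extracellular matrix genes, 19 were lower and 2 higher beyond counting error (median -0.34, percentile 0.0). Fibronectin (Fn1) was at 187 against 451 CPM (-1.27, -1.33 to -1.20) and Col1a2 at -0.79, and Thbs1 (0.76, 0.72 to 0.81) and Ccn2 (0.38) were higher. Cell division genes were lower beyond counting error in 14 of 19 and higher in 1 (median 1.62-fold, log2 -0.69, percentile 0.0). Ccnb2 (-1.61) and Cdk1 (-1.43, -1.95 to -0.94) were lowest, Tyms was within counting error (-0.09), and Aurka was higher (0.95).

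Interferon response genes were lower beyond counting error in 10 of 21 and higher in 0 (median -0.21, percentile 0.72). Mx1 (-1.66, -2.48 to -0.91) and Ifit3 (-0.74) were lowest, and Bst2 (0.07) and Gbp3 (0.02) highest. Inflammatory cytokines did not stand apart (11 measured, median -0.17, percentile 16.3). Among them Il1rn (-1.39) and the chemokine Ccl8 (-1.27, -1.70 to -0.86) were lowest, and Nfkbia (0.63) and Socs3 (0.49), feedback inhibitors of cytokine signalling, were highest. Tnf, Il6 and Il1b were all at or under 1 CPM in both libraries, where only a large difference could be seen at this depth.

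Several other cell types of fat did not follow the macrophages, unlike the mast cell and fibroblast markers above. Endothelial markers had a median of -0.02 (14 genes, percentile 19.7), with Flt1 at 0.56 and Vwf at 0.15 highest and Lyve1 (-0.50) and Tek (-0.34) lowest. Smooth muscle and pericyte markers had a median of -0.01 (percentile 34.2), with Des (0.58) and Cnn1 (0.20) highest and Cspg4 (-0.59) and Pdgfrb (-0.24) lowest. T cell markers stood apart as higher (14 genes, median 0.44, percentile 99.95), but at low counts: only Lck (0.91, 0.42 to 1.42) was beyond counting error, with Cd5 at 0.82, and Il7r (-0.43) and Cd2 (-0.32) lowest. With a pseudocount of 2 CPM the T cell median was 0.27. B cell markers (median 0.13, percentile 92.8) and lymph node stroma (0.16, percentile 87.5) did not stand apart. Pax5 (0.39) and Cd79a (0.38) were the highest B cell markers, and Ighm (-0.55) and Bank1 (-0.34) the lowest. In the node list, Ccl21a was higher (1.23) with Ccl19 at 0.76, and Cd83 (-0.78) and Cxcl13 (-0.14) were lowest. Schwann cell markers did not stand apart (median 0.04, percentile 66.7), with Prx (0.55) among the highest and Mbp lowest (-0.29). Only 2 mesothelial markers were measured, Krt19 (0.96) and Lrrn4 (0.58).

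Markers of tissues that adjoin this depot were higher in the entacapone library. Of 18 skeletal muscle genes, 16 were higher and 0 lower beyond counting error (median 1.59-fold, log2 0.67, percentile 100.0). Myh7, the slow-fibre myosin (chromosome 14, 54970684 to 54994626), was 10.2-fold higher on 142 against 15 reads, and Myh1 was at 1.70 (1.46 to 1.94). Cox6a2 (0.06) and Mylpf (0.09) were within counting error. Of 11 mammary and skin epithelium markers, 8 were higher and 0 lower beyond counting error (median 2.11-fold, log2 1.08, percentile 100.0), among them Krt1 (3.75, 1.75 to 6.88) and Krt5 (2.19), with Krt10 (0.08) and Krt18 (0.56) lowest. With a pseudocount of 2 CPM the epithelium median was 0.66. The added keratinocyte and sebaceous list gave 10 higher and 1 lower of 16 beyond counting error (median 0.88). That median was 0.53 with a pseudocount of 2 CPM and 1.51 with a minimum of 5 CPM. Krt17 (2.22) and Awat2, a wax synthase of sebaceous glands (2.21), were highest, and Pkp1 (-0.99) and Sbsn (-0.23) lowest. This list was added after the values were seen and holds Krt17, Awat2 and Cst6, which rank among the 12 highest genes. It therefore restates that ranking in part and is not separate support. Red blood cell transcripts were higher beyond counting error in 5 of 6 (median 0.70, percentile 99.98), led by the globins Hbb-bt (0.80) and Hba-a2 (0.79), with Alas2 (0.51) lowest.

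Liver transcripts were present in the vehicle library. Among the 12 lowest genes by the fixed ranking, 11 belonged to the hepatocyte list, which was added after the values were seen. These included Apoa4 (chromosome 9, 46240696 to 46243459), Fabp1, Gc, Mup20, Ttr, Apoa2, Ahsg, Ambp, Pzp and Mat1a. Apoa4 had 137 vehicle and 2 entacapone reads, a ratio of 63.5-fold with a log2 interval of -9.05 to -4.11. The others named were between 10.4-fold (Mat1a) and 15.7-fold (Mup20) lower. In the added hepatocyte list, 39 of 40 measured genes were lower beyond counting error (median 6.30-fold, log2 -2.66), with Kng1 (-4.98) next to Apoa4. Albumin (Alb) was at 66.6 against 204 CPM and Serpina3k at -1.39. Cyp2e1, which fat also expresses, was the 1 exception at 949 against 497 CPM.

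The 12 highest genes by the fixed ranking included 6 muscle or epithelial genes: Myh7, Krt17, Awat2, Krt14, Krt5 and Cst6. Krt17, Awat2 and Cst6 were counted there through the list added after the values were seen. The other 6 of the 12 were Sphk1 (sphingosine kinase), Ptx3 (a secreted pattern recognition protein), Fam13a, Ltf, Cfd and Slc43a1 (an amino acid transporter). Sphk1 was 6.52-fold higher at 21.7 against 3.33 CPM, Ptx3 4.48-fold at 87.6 against 19.5 CPM, and Slc43a1 3.44-fold at 48.4 against 14.0 CPM. Fam13a (chromosome 6, 58932090 to 59024549), a gene linked to body fat distribution, was 3.79-fold higher at 414 against 109 CPM. When the liver, muscle and epithelium lists were left out, the highest 12 also took in Cited2, Ccn1, Fam84a, Sdc4, Gsta4 and the metallothionein Mt2, at 836 against 302 CPM. The lowest 12 then included Rasd1, Itgad, Cilp, Nedd9, Bcar3, Pfkfb3, Fam20c, Clec12a, Insig1, Tph2 and Adgre1. Rasd1, a glucocorticoid-inducible small GTPase, was 5.12-fold lower at 37.7 against 193 CPM. Pfkfb3, a driver of glycolysis, was 3.18-fold lower at 181 against 576 CPM, and Itgad and Clec12a, both myeloid surface genes, were 4.64-fold and 3.77-fold lower.

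**Figure D3:**
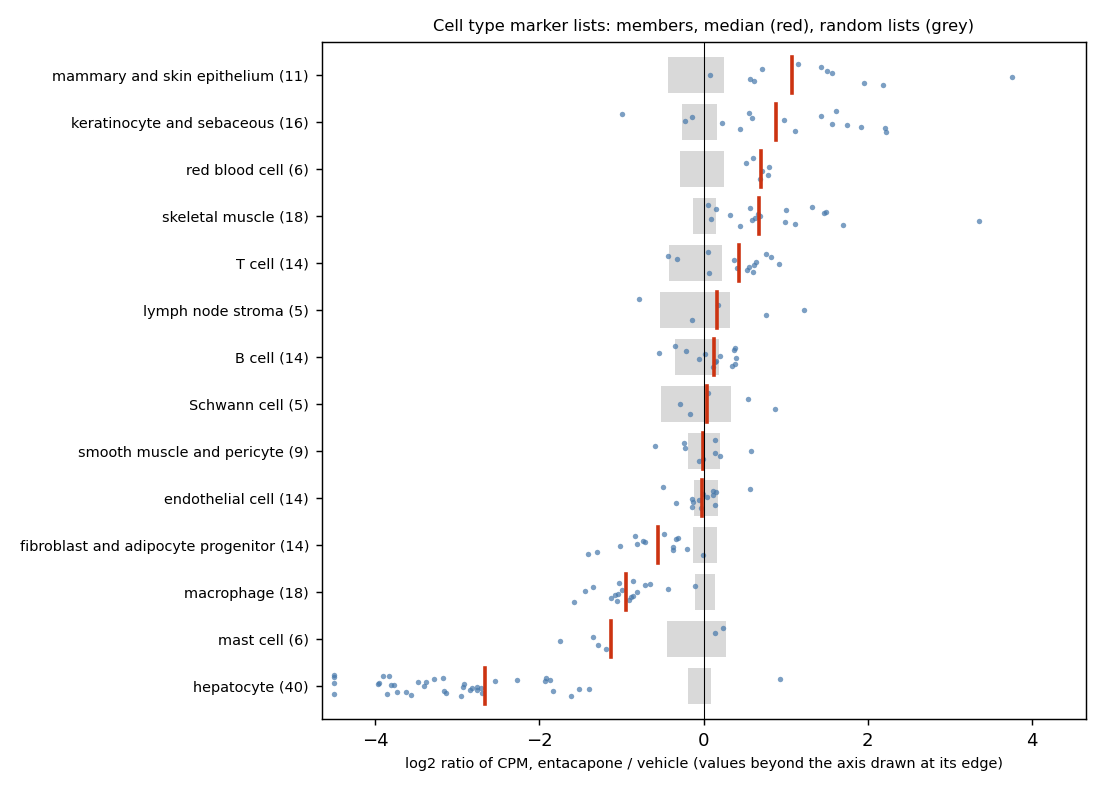
Log2 ratio of CPM (entacapone over vehicle, horizontal axis) for the members of each cell type list (points, without pseudocount; number measured in parentheses), the list median with a pseudocount of 0.5 CPM (red line) and the central 95% of 10000 random lists (grey). Macrophage (-0.94), mast cell (-1.12) and hepatocyte (-2.66) medians lie below the grey bands, and muscle (0.67) and epithelium (1.08) medians above them.

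Immediate early and heat shock genes were higher beyond counting error in 8 of 18 and lower in 1 (median 0.22, percentile 99.8). Fosb (2.33, 1.62 to 3.10) and Egr3 (1.05) were highest, Atf3 was lowest (-1.36, -1.79 to -0.95), and Fos was within counting error. Endoplasmic reticulum stress genes were lower beyond counting error in 8 of 15 and higher in 3 (median -0.20, percentile 0.41), from Ddit3 (-0.50) and Chac1 (-0.47) to Xbp1 (0.34) and Asns (0.49). This call was lost with the mean of the members (-0.12). The circadian clock list did not stand apart (17 genes, median 0.13, percentile 94.8), but members differed in both directions: Npas2 (1.20, 0.84 to 1.57) and Per1 (0.86) were higher and Bhlhe40 (-1.44, -1.73 to -1.15) and Dbp (-0.83) lower. Cytosolic ribosome genes were all above a ratio of 1 by a little (26 genes, median 0.13, percentile 95.1), from Eef1a1 (0.02) and Rpl3 (0.03) to Rps19 (0.23) and Rps24 (0.28); total-count scaling shifts all ratios by -0.04, which puts Eef1a1 and Rpl3 below a ratio of 1. With the length and GC trend removed, the ribosome median was 0.04 (percentile 60.0).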

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

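Leaving out the liver, muscle and epithelium genes and removing the length and GC trend were chosen after the data were seen. With 1 library per group, no replicate could be left out. No paired analysis was possible because each group has 1 library. The counts of 222 higher and 468 lower genes stayed within 1.5 times under DESeq2 size factors, total counts, upper-quartile scaling, thinning, no expression filter, no interval criterion and without the liver, muscle and epithelium genes. They moved to 84 and 190 with a minimum of 5 CPM, to 556 and 1056 with a 1.5-fold limit, and to 34 and 104 with a 4-fold limit, which by construction count fewer or more genes. Of 20 lists that stood apart, 15 did so under every alternative that gave a value (up to 11 each). Not all alternatives could change a call. The 3 other scalings shift all ratios almost equally, so list percentiles could hardly move. Leaving out shared members altered only the adipokine and catecholamine lists, which share Adrb3. The thermogenic list lost its call with thinning (-0.20), a minimum of 5 CPM (-0.22) and a pseudocount of 0.1 (-0.25). The triglyceride list lost it with a minimum of 5 CPM (-0.12) and the mean of members (-0.14). The catecholamine list lost it with a minimum of 5 CPM (-0.14) and the mean (-0.015), and the endoplasmic reticulum stress list with the mean (-0.12). The adipokine list turned to 0.028 with the mean, with Cfd at 1.61 among its members; the causes of these losses were not tested. Among lists that did not stand apart, none did so under any alternative, but several medians near 0 changed sign with the setting (creatine cycling, lipogenesis, lipolysis, glycolysis and smooth muscle). Fto, the other preset genes and the ranked genes with reads in both libraries kept their side of the interval under all 3 other scalings. Other list members were not recomputed singly, and one with a bound near 0, such as Ythdc2, crosses with the total-count shift. The scalings shift all ratios by -0.04 (total counts) to 0.01 (upper quartile) on the log2 scale. Below about 20 reads per library, where the interval spans a factor of 1.96 to either side, only large differences such as that of Ucp1 could be seen.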

Other observations

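Several genes outside the fixed lists also differed by more than 2-fold beyond counting error, and were chosen after their values were seen. Mt1, the companion metallothionein of Mt2, was at 1018 against 396 CPM, and Net1, a guanine nucleotide exchange factor, at 601 against 258 CPM. The transcription factor genes Cebpd (96.3 against 41.7 CPM) and Fosl2 (162 against 77.4 CPM) and the feedback inhibitor Errfi1 (61.3 against 28.8 CPM) were higher in the entacapone library. Lower were Pmepa1, a feedback inhibitor of TGF-beta signalling (158 against 425 CPM), the prostaglandin receptor Ptger3 (44.7 against 115 CPM), the oxytocin receptor Oxtr (36.6 against 93.6 CPM), and Folr2 (15.2 against 41.8 CPM) and F13a1 (54.9 against 145 CPM), both expressed by tissue macrophages.

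In the weighing that follows, the tests of the length and GC trend were set before their results were seen, and all other tests after.

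The lower macrophage markers (median log2 ratio -0.94) were weighed against 3 technical explanations. A smaller share of every non-adipocyte cell type would lower endothelial and T cell markers alike. The endothelial median was -0.020 (bootstrap interval over genes -0.14 to 0.12), which argues against an equal loss of every such type as the whole cause. The T cell median was 0.44, but only 1 of 14 T cell genes was beyond counting error. Fibroblast and progenitor markers (median -0.55) and mast cell markers (-1.12) were lower too, so a smaller share of several cell types stays open. Liver macrophages carried over with liver RNA are argued against as the whole cause by the summed vehicle excess of macrophage markers, 917 CPM, which was 1.61 times that of the hepatocyte markers, although hepatocyte transcripts outnumber macrophage transcripts in liver; Clec4f, a marker of liver macrophages, had 9 vehicle and 0 entacapone reads (0.652 CPM, 0.298 to 1.24), so a contribution from them stays open. After removal of the trend with transcript length and GC content the median was still -0.92. Fewer macrophages in this piece of tissue, an effect of the drug and chance between these 2 libraries remain open and untested.

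Of 42 hepatocyte genes with at least 20 reads, 97.6% were lower in the entacapone library beyond counting error. The list was chosen after liver genes were seen among the lowest, so this share restates the pattern and does not decide its origin. Liver RNA or reads in the vehicle library may be the cause, and expression of these genes by the fat itself, lower under the drug, stays open as well. Slc27a2 and G6pc, which liver expresses strongly, were also lower in the entacapone library, so their values may not reflect fat.

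The higher respiratory chain transcripts (median 0.23 for the nuclear genes) were weighed against 3 explanations. Removing the trend with transcript length and GC content, taken from the longest transcript of each gene, left a median of 0.14. That was still above the matched random lists, so the trend as removed could account for part of the difference. The longest transcript need not be the one expressed, so a further share of length or GC bias is not excluded. More skeletal muscle RNA was weighed with the glycolytic enzymes, taken as abundant in fast muscle, whose median was 0.0095 (bootstrap interval -0.07 to 0.14). The highest muscle marker was the slow-fibre Myh7 (10.2-fold), and Pfkm, a muscle form, was at 0.62. The glycolysis list therefore cannot decide, and muscle stays open as a cause. A higher share of adipocyte RNA cannot be told apart. The triglyceride synthesis median was -0.12 (bootstrap interval -0.23 to 0.15), below 0.23, which goes against it. The adipocyte identity median was -0.17 with members on both sides, but its interval (-0.31 to 0.42) reached above 0.23. An effect of the drug and chance between these 2 libraries stay open and untested.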
